A study of Mus musculus with 12 samples.

How the data were processed

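Small RNA was sequenced from mouse cells of 5 kinds. Androgenetic haploid embryonic stem cells (ESC) carry a single, paternal chromosome set. They were represented by the lines A129-2 (2 libraries), A129-6 (3 libraries) and A129-17 (2 libraries). R1, a diploid mouse ESC line, had 2 libraries, and round spermatids (RS), the haploid germ cells formed by meiosis, had 3 libraries. Per the labels' protocols, spermatids were sorted by Hoechst fluorescence from testes of 129Sv males, and the ESC were kept in medium with LIF and kinase inhibitors and also collected by sorting. The labels describe the replicates as independently sorted samples. Whether those of a group came from separate cultures or animals was not given in the sources used here, so SDs and p-values measure the spread between these samples, which may be technical. There was 1 diploid line, so p-values against R1 measured the spread between libraries of a line and not the spread between diploid lines. No batch, sorting date or passage was given in the labels.

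The deposited values were raw counts of reads per miRNA, with no normalisation by the authors. Per the labels' protocols, adapters were ligated to the 3' and then the 5' end of the RNA, the library was amplified by PCR and size-selected on a gel, and single-end reads were taken on a NovaSeq instrument. Bowtie 0.12.9 and DESeq2 were named per the submitters' processing notes. The genome build, the miRBase release, the treatment of reads with several matches, the use of strand and the program behind the predicted miRNA names were not given in the sources used here. The table held 1549 features, of which 1366 carried a mouse miRBase name and 183 a predicted name. All 12 columns were assigned to samples by name.

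Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Features were kept with filterByExpr by group (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR's quasi-likelihood F-test on group means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 ESC libraries were fitted together for the comparisons among ESC, and all 12 libraries for the comparisons with spermatids. The haploid lines weighed equally in the contrast of their mean against R1 or against RS. Differences between the 3 lines were tested with an F-test over the lines and then pair by pair. Fold changes are given as log2 with the standard error (SE) of the fit. Normalised CPM are counts relative to the TMM-scaled library size, as mean ± SD over the libraries of a group or, for the haploid lines together, over the 3 line means. They differ between the fit of the ESC libraries and the fit of all libraries. The let-7 family was also tested as a sum of its members, because these differ by few bases and reads can be assigned to the wrong one. Adjusted p-values come from edgeR unless another tool is named, and every test of a single miRNA was two-sided.

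Lists of miRNAs were fixed before the data were examined, as were the comparisons, the tests, the naming rule and the alternatives not described as added later. The lists were the let-7 family, the miR-290, miR-302, miR-17/92, miR-200 and miR-183 clusters or families, the miR-34 and miR-449, miR-15/16 and miR-29 families, the imprinted Dlk1-Dio3 region, the miRNA families in an intron of Sfmbt2, miRNAs of other paternally expressed hosts, miR-675 of H19, an X-linked cluster enriched in testis, miR-202, and markers of mesenchymal cells, of blood and endothelium, and of differentiated lineages. Each list with at least 3 tested members was compared with all other miRNAs by limma's camera test with a preset correlation of 0.01, and again with an estimated correlation. Members past the threshold were counted over all miRNAs and also adjusted over the list alone.

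The naming rule took the let-7 family, the largest changes with the same sign in all 3 lines and a mean CPM of at least 10, the members with the highest CPM in each list, the most abundant miRNAs per group and the smallest p between lines. For length, and after the data had been seen, list members were named only for lists that passed with the preset correlation and for the miR-290 cluster against R1, with 2 members per list in the comparisons with RS. A few further miRNAs are named where the text says that they were chosen after their values were seen.

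Where every library of a group had a count of 0, the fold was bounded by a floor of 3 counts over the whole group. Such a bound, written with the words at least, holds for the TMM-scaled library sizes and would change with another scaling. For 1 to 3 counts a ratio of pooled counts with a 95% Poisson interval is given. The same ratio, with the levels, is given, a choice made after the data had been seen, in place of the fitted fold where a decrease in the haploid lines rested on a line with 0 counts. Shares and CPM of single libraries have exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Total counts ran from 3709786 to 9176080 in the ESC libraries and from 155232 to 243714 in the spermatid libraries, so that 3 counts were worth 0.327 to 0.809 CPM in ESC and 12.3 to 19.3 CPM in spermatids. These totals are of reads counted to miRNAs, not of all reads sequenced. The replicates were compared by chi-square tests of their counts. The smallest chi-square per degree of freedom was 52.6, between the R1 libraries, so no pair agreed within sampling noise.

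Of the named miRNAs, 1325 were matched by name to precursors in the GENCODE M21 annotation of GRCm38. The GC content of an arm was estimated from the 22 bases beside the terminal loop of the precursor folded with ViennaRNA 2.7.2, because the mature sequences were not used here. Precursors that overlap on opposite strands, and features with identical counts, were listed and are reported as uncertain. Some such partners had nearly equal counts (miR-136-3p and miR-3071-5p had a ratio of 1.02, miR-374b-5p and miR-374c-3p 1.00), so that the reads of these pairs cannot be told apart. Others differed (3.55 for miR-292a-5p and miR-292b-3p, 141 for miR-337-5p and miR-3544-3p), and because the use of strand was not given, part of their counts may be shared.

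The alternatives were other scalings (RLE, upper quartile, total count, and the miR-290 cluster left out of the scaling), no filter or a stricter one, DESeq2 1.42.0, a replicate block, each library left out in turn, another set of libraries in the fit, and counts summed per cell line. Added after seeing the data were a correction for arm GC (a loess of log CPM deviations per library, span 0.75), the same features without that correction, leaving out the 2 libraries with the lowest TMM factors (A129-6 replicate 3 and A129-17 replicate 1), thinning the ESC libraries to the depth of the median spermatid library (166695 counts), and leaving out the less abundant of antisense or identical features (24 features). The closing part gives their effect. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and list members with very low counts are drawn at their fitted values.

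The tests were tried on simulated counts with known changes. For the tests of single miRNAs, a minority of miRNAs was changed, with as many raised as lowered. These simulations therefore cannot show false calls that the scaling may bring where most miRNAs differ. For the haploid lines against R1, edgeR recovered 42.6% of 2-fold and 81.9% of 4-fold changes among 705 miRNAs, with 2 false calls. For the haploid lines against RS it recovered 27.5% and 56.8% among 743 miRNAs, with 5 false calls among 80. For R1 against RS it recovered 14.9% and 58.4% among 726, with 1 false call among 66. For the test between lines it recovered 37.2% and 75.5% among 709 miRNAs, with 4 false calls among 113, where DESeq2 had 16 among 141. With a simulated GC trend among 675 miRNAs, the correction lowered false calls in the comparison of haploid lines with R1 from 187 to 8. In a simulation of that comparison over 757 miRNAs, camera found all 15 changed lists and called 0 of 210 unchanged ones. The simulated miRNAs varied independently of each other, and all members of a changed list shifted alike. This simulation therefore cannot show how the preset correlation performs on lists whose members vary together.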

Results

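The series profiled miRNAs of mouse androgenetic haploid ESC beside a diploid ESC line and round spermatids, and its title concerns let-7a and the tendency of haploid ESC to become diploid. Counted reads were 3709786 and 9102467 in A129-2, 7206045, 6287047 and 7282355 in A129-6, 6889407 and 5603025 in A129-17, and 7632174 and 9176080 in R1. The spermatid libraries were much shallower, with 243714, 155232 and 166695 counts. Between 883 and 1086 miRNAs had a count in an ESC library and 491 to 543 in a spermatid library. In a principal component analysis of all libraries, the first component held 73.0% of the variance and separated spermatids from ESC, and the second held 15.6% and separated R1 from the haploid lines.

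The most abundant miRNA of every ESC library was miR-292a-5p of the miR-290 cluster, the main miRNA cluster of mouse pluripotent cells (9 annotated precursors on chromosome 7, 3218626 to 3220841, GRCm38). It took 35.6% to 56.9% of counts in the haploid lines and 14.8% to 15.1% in R1. The whole cluster took 64.1% to 77.1% and 49.1% to 50.2%. In A129-2, A129-6 and A129-17 the next most abundant miRNAs were miR-292b-3p, miR-292a-3p, miR-293-3p and miR-127-3p or miR-151-3p. In R1 they were miR-293-5p, miR-293-3p, miR-21a-5p and miR-7a-5p. On average spermatids were led by miR-34c-5p, with 86945 ± 44830 normalised CPM (SD, n = 3). Then came miR-881-3p with 49268 ± 36722, miR-21a-5p with 41647 ± 24406, miR-148a-3p with 24646 ± 15105 and miR-143-3p with 18514 ± 14494. RS replicate 1 was led by miR-881-3p (17.2% of counts), and replicates 2 and 3 by miR-34c-5p (23.2% and 28.7%). The miR-34 and miR-449 families took 8.75%, 25.1% and 30.6% of counts in RS replicates 1, 2 and 3.

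let-7a-5p, a miRNA of differentiated cells that has precursors on chromosome 13 (48538179 to 48538272) and chromosome 9 (41536716 to 41536811, both GRCm38), was present in every library. Relative to total counts it reached 938 ± 443 CPM in A129-2 (SD, n = 2), 836 ± 61.2 in A129-6 (n = 3), 1031 ± 415 in A129-17 (n = 2), 205 ± 11.1 in R1 (n = 2) and 10682 ± 1779 in RS (n = 3). The highest R1 library had 213 CPM (95% interval 203 to 222), below every haploid library.

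How the haploid ESC differed from diploid ESC was asked first. let-7a-5p was higher in all 3 haploid lines, with 952 ± 226 normalised CPM (SD of 3 lines) against 189 ± 3.78 in R1 (n = 2), a 4.93-fold difference (log2 2.30, SE 0.29, adjusted p = 4.67e-06). Over the alternatives the log2 difference ran from 2.07 with RLE scaling to 3.15 with all 12 libraries in the fit, and it was 2.97 after GC correction, and the call was kept in each. The log2 difference was 2.04 in A129-2, 2.20 in A129-6 and 2.67 in A129-17 (SE 0.32, 0.31 and 0.33). let-7b-5p (log2 3.62, SE 0.37), let-7e-5p (3.07, SE 0.26), let-7d-5p (2.19, SE 0.35), let-7c-5p (1.89, SE 0.27) and let-7i-5p (1.54, SE 0.25) rose as well. let-7g-5p was lower by the main scaling (log2 -0.51, SE 0.20, adjusted p = 0.0349), but its sign turned with all 12 libraries in the fit (0.35) and after GC correction (0.03). Its call was lost with upper-quartile (adjusted p = 0.428) or total-count scaling (0.0863), no filter (0.0811), the stricter filter (0.546) or sums per line (0.213), and without A129-6 replicate 1 (adjusted p = 0.0894) or 2 (0.0596), A129-17 replicate 1 (0.0563) or R1 replicate 1 (0.202) or 2 (0.237). let-7f-5p stood at 0.21 (adjusted p = 0.397), with its sign turned by RLE scaling (-0.03), and miR-98-5p stood at -0.03 (adjusted p = 0.938), with its sign turned by upper-quartile scaling (0.29). The summed let-7 family was 2.12-fold higher in the haploid lines (log2 1.08, SE 0.24, adjusted p = 0.000893), with 5130 ± 628 normalised CPM in A129-2, 5293 ± 594 in A129-6, 6062 ± 1317 in A129-17 and 2587 ± 103 in R1. The log2 difference was 1.83 with all 12 libraries in the fit and 1.86 after GC correction. When counts were summed per line it was 0.94 with an adjusted p of 0.0605, the highest over the alternatives, which reached down to 1.93e-05. Of the 9 family members 6 rose, 1 fell and 2 did not pass, also when adjusted over the list alone, and the list was higher than other miRNAs (adjusted p = 0.0220). It had an adjusted p = 0.544 with an estimated correlation, and passed neither with total-count scaling (0.0515) nor with the stricter filter (0.0509).

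**Figure D1:**
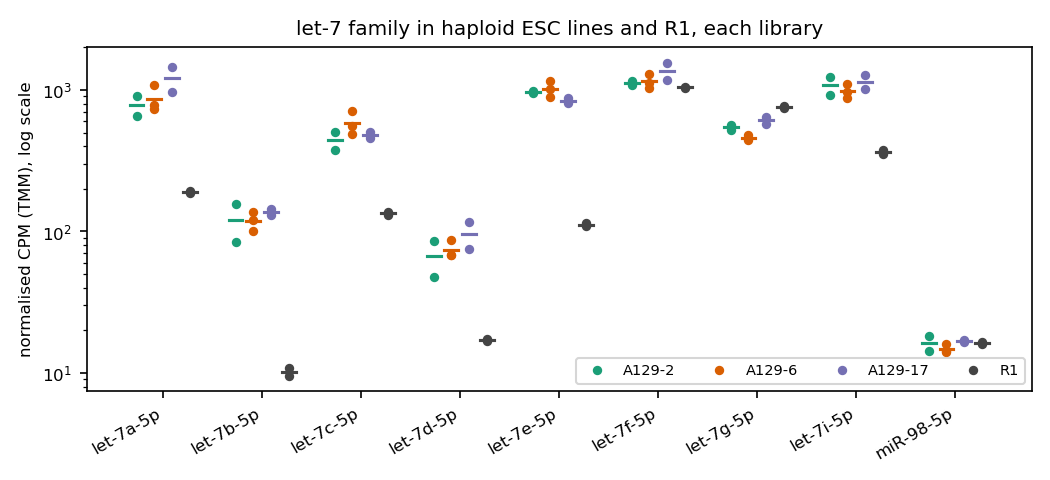
Normalised CPM of the 9 let-7 family members on a log axis, with a point for each library of the haploid lines A129-2, A129-6 and A129-17 and of R1 and a bar for each group mean. let-7a-5p averaged 952 in the haploid lines and 189 in R1, while let-7f-5p, let-7g-5p and miR-98-5p lay near R1. The sign of the difference changed with the scaling for let-7f-5p and miR-98-5p, and for let-7g-5p with all 12 libraries in the fit and after GC correction.

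Of 757 miRNAs tested between the haploid lines and R1, 534 changed, 267 higher and 267 lower, and 489 changed at least 2-fold. Without the 2 libraries of lowest TMM factor the count was 573. With all 12 libraries in the fit the median log2 difference shifted by 0.85 and 66.0% of the called miRNAs were higher, against 267 of 534 here, and RLE and upper-quartile scaling shifted it by -0.24 and 0.31. The largest increases with at least 10 CPM in a group included 6 miRNAs of chromosome X, which were miR-504-5p (log2 6.04, SE 0.35), miR-470-5p (5.72, SE 0.49), miR-465a-3p (5.34, SE 0.54), miR-878-3p (5.22, SE 0.46), miR-871-3p (5.22, SE 0.52) and miR-743a-5p (5.01, SE 0.57). The others were miR-12182-3p (6.27, SE 0.92), miR-214-3p (5.04, SE 0.47), miR-211-3p (4.71, SE 0.57) and miR-1964-3p. The last had 1 count in R1 and 412 in the haploid lines, a ratio of 167 (95% interval 29.9 to 6623). The largest decreases were miR-376c-3p, from 206 ± 24.6 normalised CPM in R1 to 1.20 ± 0.62 in the haploid lines (log2 -7.51, SE 0.48), miR-335-5p (-7.20, SE 0.49), miR-32-5p (-6.76, SE 0.48), miR-19b-3p (-6.70, SE 0.41), miR-19a-3p (-6.33, SE 0.50), miR-136-3p (-6.08, SE 0.24) and miR-369-3p (-5.84, SE 0.41). Also among them were miR-96-3p and miR-377-3p, both with 0 counts in A129-17. miR-96-3p was at 12.9 ± 1.70 normalised CPM in R1 and 0.20 ± 0.25 in the haploid lines (ratio of pooled counts 58.4, 95% interval 31.2 to 123), and miR-377-3p at 15.2 ± 1.48 and 0.48 ± 0.42 (ratio 27.1, interval 18.0 to 42.6). miR-3071-5p, antisense to miR-136-3p with nearly the same counts, is uncertain. All of these had adjusted p-values of 3.69e-05 or less.

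Members of the miR-290 cluster differed in opposite directions. miR-293-5p fell from 91455 ± 92.5 normalised CPM in R1 to 2375 ± 265 in the haploid lines, a 38.7-fold decrease (log2 -5.27, SE 0.24, adjusted p = 8.54e-11), and miR-293-3p fell by 1.25 on the log2 scale (SE 0.27), a call lost with all 12 libraries in the fit (-0.40, adjusted p = 0.712). miR-292a-5p rose by 1.83 (SE 0.39), as did miR-292b-3p (1.59, SE 0.27), which is antisense to it and uncertain. Of 18 tested members 4 rose, 8 fell and 6 did not pass, the same counts as when adjusted over the list alone, and the list test did not pass (adjusted p = 0.590).

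miRNAs of the Dlk1-Dio3 region, an imprinted locus whose miRNAs are transcribed from the maternal chromosome (60 annotated precursors on chromosome 12, 109544541 to 109747960, GRCm38), were mostly lower in the haploid lines. Of 93 tested, 55 fell, 20 rose and 18 did not pass, and the counts adjusted over the list alone were also 55 and 20. After GC correction 63 fell and 8 rose, and with all 12 libraries in the fit 37 of 92 fell and 28 rose. The region still took 4.52% to 8.80% of counts in the haploid libraries, against 8.46% to 9.02% in R1. It was thus lower for many members but not silent. miR-379-5p fell 9.78-fold (log2 -3.29, SE 0.21) and miR-411-5p 2.00-fold (SE of the log2 difference 0.23), the latter not called with all 12 libraries in the fit (-0.16, adjusted p = 0.784). miR-127-3p was higher (log2 0.69, SE 0.27, adjusted p = 0.0341), a call lost with RLE (adjusted p = 0.139) or total-count scaling (0.139), DESeq2 (0.149), the miR-290 cluster left out of the scaling (0.0744), no filter (0.0712), sums per line (0.240) and GC correction (0.508), and without R1 replicate 1 (0.253), R1 replicate 2 (0.136) or A129-17 replicate 2 (0.0979), with adjusted p from 0.00428 to 0.508 over the alternatives. miR-541-5p was not called (-0.31, adjusted p = 0.469) and changed sign with upper-quartile scaling (0.02). The list was lower than other miRNAs (adjusted p = 0.000119), with an adjusted p = 0.213 with an estimated correlation.

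The families in an intron of Sfmbt2, a paternally expressed gene, were mostly higher. Of 54 tested members 34 rose, 2 fell and 18 did not pass, and adjusted over the list alone also 34 rose and 2 fell. miR-669c-5p rose 6.77-fold (log2 2.76, SE 0.30) and miR-669a-5p 1.83-fold (0.87, SE 0.26), which did not pass without R1 replicate 1 (adjusted p = 0.0750) or 2 (0.108), with total-count scaling (0.0731) or with sums per line (0.181). miR-467a-5p and miR-467b-5p, which had identical counts and are uncertain, stood at -0.44 (adjusted p = 0.0823) and changed sign with all 12 libraries in the fit (0.42). The list had an adjusted p = 0.000119, and an adjusted p = 0.544 with an estimated correlation. Of 7 miRNAs of other paternally expressed hosts, 4 rose and 3 fell, counts that were the same adjusted over the list alone, and the list did not pass (adjusted p = 0.865). Its median was positive. miR-675 of H19 took at most 6.94e-05% of any library and was not tested.

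The X-linked cluster (19 annotated precursors on chromosome X, 66776757 to 66839125, GRCm38), whose miRNAs are best known from testis, was higher in the haploid lines for 16 of 24 tested members, lower for 4 and not called for 4. Adjusted over the list alone, 17 rose and 4 fell. miR-871-3p reached 5556 ± 3499 normalised CPM in the haploid lines against 124 ± 14.5 in R1, and miR-465c-5p rose by log2 4.00 (SE 0.43). miR-881-3p, chosen after its value was seen because it was the most abundant member in spermatids, fell by 1.06 (SE 0.31). It was not called after GC correction (-0.51, SE 0.33, adjusted p = 0.181), with all 12 libraries in the fit (-0.19, adjusted p = 0.789), upper-quartile scaling (-0.74, 0.0536), the stricter filter (-0.67, 0.0946) or sums per line (-1.07, 0.121). After GC correction 19 members of the cluster were higher and 1 lower. The list had an adjusted p = 0.00451, and an adjusted p = 0.554 with an estimated correlation.

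The miR-183 cluster and the miR-200 family, which are expressed in ESC and epithelia, were lower. miR-182-5p fell 16.1-fold, from 44025 ± 6183 normalised CPM in R1 to 2796 ± 716 in the haploid lines (log2 -4.01, SE 0.26), miR-96-5p fell 42.8-fold (log2 -5.42, SE 0.27) and miR-183-5p 3.83-fold (log2 -1.94, SE 0.24). miR-183-3p was not called (-0.22, adjusted p = 0.497) and changed sign with upper-quartile scaling (0.10). Of 6 members of the miR-183 cluster 5 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.00451, and adjusted p = 0.213 with an estimated correlation). miR-200a-3p fell 13.5-fold (log2 -3.75, SE 0.21), miR-429-3p 10.8-fold (log2 -3.43, SE 0.25), miR-200b-3p 3.79-fold (log2 -1.92, SE 0.20) and miR-200c-3p 3.65-fold (log2 -1.87, SE 0.24). Of 8 tested members of the miR-200 family 7 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.00711, and adjusted p = 0.215 with an estimated correlation). After GC correction the adjusted p was 0.0932 for the miR-183 cluster and 0.221 for the miR-200 family, and with the stricter filter it was 0.0582 for the miR-183 cluster. The median log2 difference went from -3.03 to -3.52 and from -2.35 to -2.18 with GC correction, and again 5 and 7 members were lower.

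The miR-17/92 list holds that cluster, which promotes proliferation, together with its paralogs at other loci. Its members went both ways. miR-92a-3p rose from 2621 ± 89.7 normalised CPM in R1 to 12155 ± 1036 in the haploid lines (log2 2.21, SE 0.25), while miR-93-5p fell 2.14-fold (log2 -1.10, SE 0.25) and miR-25-3p 2.09-fold (log2 -1.07, SE 0.22). With all 12 libraries in the fit neither of the last passed (-0.23 and -0.22, adjusted p = 0.642 and 0.624). miR-106b-3p was not called (0.19, adjusted p = 0.477) and changed sign with RLE scaling (-0.06). Of 23 tested members 16 fell, 6 rose and 1 did not pass, also when adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.544 with an estimated correlation). The list passed neither after GC correction (adjusted p = 0.0921) nor with the stricter filter (0.0909). GC correction took its median from -1.50 to -1.99, with 17 members lower and 4 higher, and with all 12 libraries in the fit 10 were lower and 7 higher.

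The remaining lists did not differ from other miRNAs by the set test. In the miR-302 cluster 5 of 8 tested members fell and 1 rose (adjusted p = 0.590), and adjusted over the list alone 6 fell. After GC correction 1 miR-302 member was lower and 1 higher, with the median going from -0.93 to -0.29, and with all 12 libraries in the fit 0 were lower and 1 higher. In the miR-15/16 family 5 of 7 fell and 1 rose (adjusted p = 0.0976), and in the miR-34 and miR-449 families 2 of 4 fell and 1 rose (adjusted p = 0.980). The last list had a positive median and a test in the downward direction, and after GC correction 0 of its members were lower and 1 higher. The markers of other cell types moved both ways. Of 11 mesenchymal markers 3 rose and 5 fell (adjusted p = 0.590), of 7 blood and endothelial markers 3 rose and 4 fell (adjusted p = 0.136, with 1 higher and 4 lower after GC correction), and of 12 markers of differentiated lineages 5 rose and 5 fell (adjusted p = 0.980, with a negative median and a test in the upward direction). Except for miR-302, the counts of these lists were the same when adjusted over the list alone. The miR-29 family had 2 tested members, too few for the set test.

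**Figure D2:**
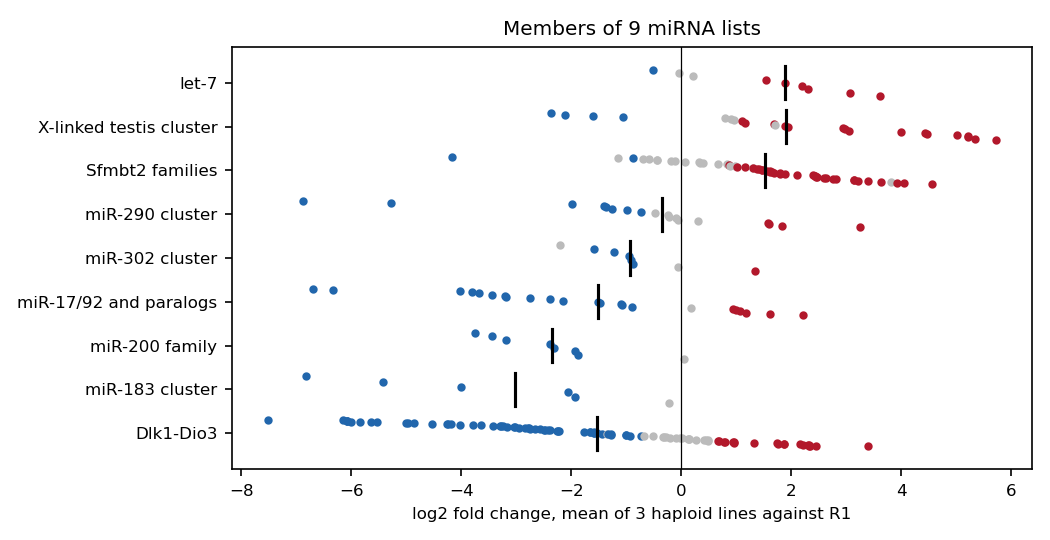
Log2 fold change of the mean of the 3 haploid lines against R1 for each tested member of 9 lists, with members that rose in red, members that fell in blue, members that did not pass in grey and a black bar at the median. Dlk1-Dio3 holds 55 decreases among 93 members and the Sfmbt2 families 34 increases among 54, and single members near 0 changed sign with the scaling.

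The differences between haploid lines and R1 went with the GC content of the miRNA. Across the 440 miRNAs with a GC estimate and a mean log2 CPM above 3, Spearman's rho of fold change and GC was 0.290 and Pearson's r 0.289 (permutation p = 1e-05, the smallest that the 100000 permutations can give). These are correlations across miRNAs, which are not independent replicates. The median log2 fold change was -1.09 among 102 miRNAs of 35 to 45% GC and 1.45 among 73 miRNAs of 55 to 65% GC, but 0.96 among the 25 below 35%. Within libraries, rho of GC and the deviation from the mean level was -0.300 and -0.280 in R1 and 0.114 to 0.360 in the haploid lines. After the correction for GC 494 of 719 miRNAs passed, against 526 of the same miRNAs without it, and 437 passed in both.

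**Figure D3:**
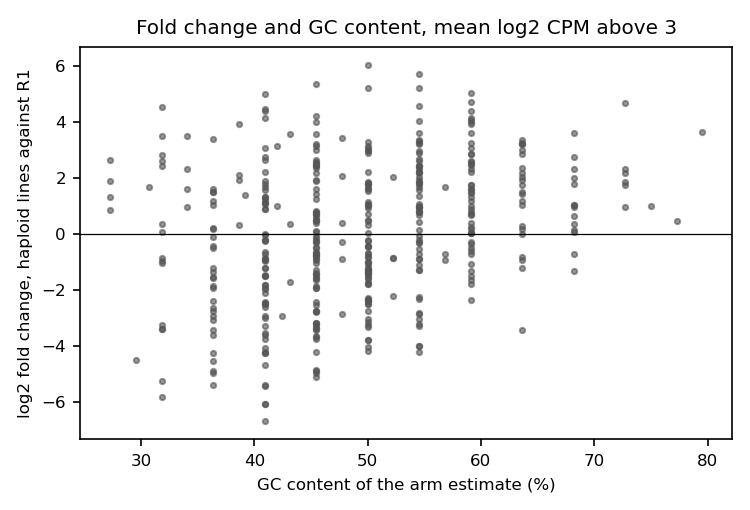
Log2 fold change of the haploid lines against R1 plotted against the estimated GC content (%) of the miRNA arm, with a point for each of the 440 tested miRNAs of mean log2 CPM above 3 that had a GC estimate. Points scatter widely from 35 to 65% GC, and the median was -1.09 from 35 to 45% GC and 1.45 from 55 to 65% GC.

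Each haploid line was then compared with R1. let-7a-5p was higher and miR-293-5p lower in every line, the latter with log2 -5.20 in A129-2, -5.16 in A129-6 and -5.46 in A129-17 (SE 0.38, 0.32 and 0.39, adjusted p of 7.95e-08 or less). In A129-2 453 miRNAs changed (235 higher, 218 lower), in A129-6 508 (265 higher, 243 lower) and in A129-17 501 (262 higher, 239 lower). In all 3 lines together 196 miRNAs were higher and 190 lower. The lines share the R1 libraries. Simulated unchanged lines against those controls gave on average 0.05 and 0, and independent lists of the same lengths would share 28.5 and 22.1. The covariance of the log2 fold changes was 6.80 for A129-2 and A129-6, 7.24 for A129-2 and A129-17 and 7.84 for A129-6 and A129-17, against 0.172, 0.177 and 0.171 in the simulations. With 2 R1 libraries the controls could not be split with 2 on each side. Part of the excess may therefore come from the shared controls, through effects particular to the R1 libraries that the simulations leave out.

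How far the haploid lines differed from each other was asked next. miR-210-3p, a miRNA induced by hypoxia, was at 91.6 ± 55.2 normalised CPM in A129-6 (SD, n = 3), 19.9 ± 1.66 in A129-2 and 21.8 ± 1.96 in A129-17 (n = 2 each). miR-504-5p was at 430 ± 37.5 in A129-2, 161 ± 16.4 in A129-6 and 297 ± 51.7 in A129-17. miR-25-5p was highest in A129-17 (216 ± 27.5, against 85.4 ± 9.79 in A129-2 and 85.8 ± 5.63 in A129-6), as were miR-149-5p (316 ± 2.79, against 110 ± 22.4 and 147 ± 18.0), miR-92a-2-5p (57.7 ± 18.7, against 13.4 ± 3.53 and 19.2 ± 5.80) and miR-3473b (133 ± 6.15, against 29.4 ± 29.7 and 23.3 ± 2.00). All 6 had an adjusted p of 0.0394 in the F-test over the lines. The let-7 family sum did not differ between lines, with log2 differences of 0.05, 0.24 and 0.20 (SE 0.26, 0.28 and 0.26, lowest adjusted p = 0.635). Of 757 miRNAs 29 differed between lines and 174 had an unadjusted p under 0.05. Pair by pair, edgeR called 18 between A129-6 and A129-2 (14 higher and 4 lower in A129-6, 103 at an unadjusted p under 0.05). It called 0 between A129-17 and A129-2 (181 unadjusted) and 0 between A129-17 and A129-6 (123 unadjusted), where DESeq2 called 62 and 23. These counts rest on few libraries, since the F-test called 0 with A129-6 replicate 1 or 2 left out, 6 or 9 with a library of A129-2 left out, 44 without A129-17 replicate 2 and 80 without A129-6 replicate 3. Total-count scaling gave 0, all 12 libraries in the fit 2, the stricter filter 4, no filter 82 and DESeq2 85.

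The haploid ESC were also compared with round spermatids, germ cells that also hold a single chromosome set. let-7a-5p was lower in the haploid lines, with 1415 ± 370 normalised CPM (SD of 3 lines) against 4910 ± 1329 in RS (n = 3; log2 -1.83, SE 0.30, adjusted p = 9.68e-06), and log2 -3.52 with total-count scaling to -1.70 without A129-2 replicate 1 over the alternatives. let-7g-5p (log2 -2.86, SE 0.28), let-7b-5p (-1.68, SE 0.27), let-7f-5p (-1.06, SE 0.33) and let-7i-5p (-0.95, SE 0.31) fell too, let-7e-5p rose (4.12, SE 0.46), and let-7d-5p (-0.43, adjusted p = 0.233) and miR-98-5p (-0.89, adjusted p = 0.0591) were not called. let-7c-5p was not called either (0.33, adjusted p = 0.298) and was lower with upper-quartile (-1.24) or total-count scaling (-1.39). The family sum was lower (log2 -1.39, SE 0.33, adjusted p = 0.000800, and log2 -2.92 to -1.31 over the alternatives, the former with total-count scaling), with 20514 ± 6099 normalised CPM in RS. Of 9 members 1 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.0416, and adjusted p = 0.428 with an estimated correlation). With GC correction 8 members were lower and 1 higher, and their median went from -0.95 to -2.35, while that of all miRNAs also shifted downward. The list call was also lost after GC correction (adjusted p = 0.142), with the stricter filter (0.0851), with antisense or identical features left out (0.0674), with only the groups compared in the fit (0.0668), with the miR-290 cluster left out of the scaling (0.0604), and without RS replicate 1 (0.130), 2 (0.0695) or 3 (0.0735) or A129-6 replicate 1 (0.0640). Those of let-7f-5p and let-7i-5p were lost without RS replicate 1 (adjusted p = 0.0714 and 0.0540) or A129-2 replicate 1 (both 0.0507). In the same libraries, blood and endothelial markers took 0.821% ± 0.668 of counts in RS (SD, n = 3) and 0.0629% ± 0.0199 in the 7 haploid libraries, and mesenchymal markers 4.81% ± 2.30 and 1.25% ± 0.723.

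Of 806 miRNAs 527 changed between haploid lines and RS, 359 higher and 168 lower. Among the named miRNAs, those with 0 counts in RS included miR-291b-5p of the miR-290 cluster, at least 1424-fold higher in the haploid lines, miR-673-5p (at least 164-fold), miR-431-3p (at least 91.9-fold), miR-302a-3p (at least 86.7-fold), miR-344-3p (at least 85.4-fold), miR-667-3p (at least 81.5-fold), miR-431-5p (at least 75.5-fold) and miR-673-3p (at least 73.5-fold). In the other direction miR-7210-5p, at 4413 ± 3405 normalised CPM in RS (SD, n = 3), had 0 counts in the haploid lines and was at least 46733-fold lower. Likewise lower were miR-468-5p (at least 28301-fold), miR-7214-5p (at least 9261-fold), miR-7230-5p (at least 2751-fold), the predicted novel_697 (at least 1347-fold) and miR-7217-5p (at least 901-fold). miR-449a-5p, with 0 counts in A129-2, was at 1642 ± 931 in RS and 0.52 ± 0.59 in the haploid lines (SD of 3 lines), a ratio of pooled counts of 3371 (95% interval 2004 to 6177). miR-34b-5p, with 0 counts in A129-6 and A129-17, was at 259 ± 129 and 0.22 ± 0.38 (ratio 1495, interval 634 to 4637). The bounds above hold for TMM-scaled library sizes. Lower limits of the 95% Poisson intervals were smaller, at 1158 for miR-291b-5p, 133 for miR-673-5p and 37994 for miR-7210-5p. TMM factors ran from 1.89 to 2.63 in RS and from 0.469 to 1.03 in the haploid libraries. Scaling by total counts alone would therefore lower the bounds of miRNAs absent from RS.

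Among the lists, the pluripotency clusters were higher in the haploid lines. In the miR-290 cluster 17 of 18 members rose and 0 fell, with miR-292a-5p higher by log2 11.40 (SE 1.42) and miR-292b-3p by 10.92 (SE 1.19). The list had an adjusted p = 1.36e-06, and an adjusted p = 0.280 with an estimated correlation. RS replicate 2 held 0.678% of its counts (95% interval 0.637 to 0.720) in this cluster, against 0.00985% (0.00631 to 0.0147) and 0.0432% (0.0338 to 0.0544) in the other spermatid libraries, and without it 495 miRNAs changed between haploid lines and RS and 456 between R1 and RS. miR-292a-5p had 3, 300 and 29 counts in RS replicates 1, 2 and 3, and miR-292b-3p had 1, 111 and 13. Without RS replicate 2 their log2 differences were 14.25 and 13.62. In the miR-302 cluster 7 of 8 rose and 0 fell (adjusted p = 0.0279, and adjusted p = 0.349 with an estimated correlation). All 8 of its counts in RS lay in replicate 2. With that library miR-302a-5p (5 counts) rose by 7.09 (SE 0.65) and miR-302b-3p (2 counts) was higher by a ratio of 357 (95% interval 98.9 to 2949). Without it both had 0 counts in RS and were at least 178-fold and 160-fold higher, with the floor of 3 counts over the other 2 libraries. In Dlk1-Dio3 77 of 92 rose and 0 fell (adjusted p = 8.53e-10, and adjusted p = 0.149 with an estimated correlation), with miR-370-3p at 10.78 (SE 0.78) and miR-127-3p at 8.32 (SE 0.66). Without RS replicate 2 miR-127-3p stood at 9.14, and miR-370-3p, then with 2 counts in RS, was higher by a ratio of 5711 (95% interval 1581 to 47158). In the Sfmbt2 families 38 of 53 rose and 2 fell (adjusted p = 0.000656, and adjusted p = 0.382 with an estimated correlation), while miR-467a-5p and miR-467b-5p stood at 0.47 (adjusted p = 0.272) and were lower with total-count scaling (-1.21). Adjusted over the list alone the counts were the same except for 39 Sfmbt2 increases.

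Lists lower in the haploid lines were led by germ-cell miRNAs. In the miR-34 and miR-449 families, abundant in post-meiotic male germ cells, 6 of 7 fell and 1 rose (adjusted p = 3.72e-05, and adjusted p = 0.149 with an estimated correlation), with miR-34c-5p at 193 ± 82.8 normalised CPM in the haploid lines and 86945 ± 44830 in RS (log2 -8.90, SE 0.50) and miR-34b-3p at -8.89 (SE 0.36). In the X-linked cluster 20 of 25 fell and 1 rose (adjusted p = 1.82e-09, and adjusted p = 0.149 with an estimated correlation). miR-881-3p fell by 6.76 (SE 0.49) and miR-871-3p by 1.08 (SE 0.39), the latter not called without A129-2 replicate 1 (adjusted p = 0.141) or with sums per line (0.0542). In the miR-15/16 family 5 of 7 fell and 1 rose (adjusted p = 0.00877, and adjusted p = 0.312 with an estimated correlation), with miR-16-5p at -3.81 (SE 0.31) and miR-15b-5p at -1.56 (SE 0.29). That list did not pass after GC correction (adjusted p = 0.0821) or thinning (0.0526). With GC correction its median went from -3.36 to -5.05 and again 5 members were lower, while the median of all miRNAs also shifted downward. All 3 tested miR-29 miRNAs fell, miR-29a-3p by 2.49 (SE 0.28) and miR-29b-3p by 2.51 (SE 0.63; adjusted p for the list = 0.0395, and adjusted p = 0.25 with an estimated correlation). The miR-29 list did not pass without RS replicate 1 (adjusted p = 0.0843), 2 (0.163) or 3 (0.0768) or A129-6 replicate 1 (0.0616), after GC correction (0.168), with antisense or identical features left out (0.0674), with only the groups compared in the fit (0.0668), with counts summed per line (0.0613) or with the miR-290 cluster left out of the scaling (0.0604). Of 9 blood and endothelial markers 8 fell and 1 rose (adjusted p = 0.00555, and adjusted p = 0.345 with an estimated correlation), with miR-126a-3p at -5.36 (SE 0.50) and miR-150-5p at 4.33 (SE 0.46), the latter not called after GC correction (0.21, adjusted p = 0.690). These markers took 1.50%, 0.159% and 0.808% of counts in RS replicates 1, 2 and 3 and 0.0369% to 0.0873% in the haploid libraries. Of 12 markers of differentiated lineages 8 fell and 1 rose (adjusted p = 0.0104, and adjusted p = 0.149 with an estimated correlation), with miR-375-3p at -7.49 (SE 0.36) and miR-128-3p at -2.54 (SE 0.29). With the stricter filter neither list of markers passed (both adjusted p = 0.05005), and the blood and endothelial list did not pass after thinning (0.106). Adjusted over the list alone the counts were the same except for 2 lineage increases.

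The lists that did not pass against RS were miR-17/92 (16 of 23 rose, 3 fell, adjusted p = 0.182, with 4 decreases adjusted over the list alone), miR-200 (2 of 7 rose, 2 fell, adjusted p = 0.324), miR-183 (4 of 6 rose, 0 fell, adjusted p = 0.386), other paternally expressed hosts (4 of 7 rose, 1 fell, adjusted p = 0.187) and mesenchymal markers (2 of 11 rose, 5 fell, adjusted p = 0.168). The last 4 had the same counts adjusted over the list alone. miR-202-5p had 45 counts in RS and 3 in the haploid lines, a ratio of 365 (95% interval 117 to 1837), and was not tested as a list. The scaling moved this comparison. Total-count scaling shifted the median log2 difference by -1.68 and made 46.1% of the called miRNAs higher, against 68.1% with TMM, and GC correction shifted it by -1.48 and left 37.7% higher. Upper-quartile scaling (-1.56, 48.6% higher) and thinning to the spermatid depth (-1.06, 53.0% higher, 336 calls) moved it as well. With total-count scaling 8 let-7 members, 5 of the miR-200 family and 9 mesenchymal markers were lower, 20 Sfmbt2 members were higher and 7 lower, 10 miR-17/92 members were higher and 5 lower, and 55 Dlk1-Dio3 members were higher and 3 lower.

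R1 was set against the spermatids in the same way. let-7a-5p was lower in R1, with 156 ± 8.66 normalised CPM (SD, n = 2) against 4910 ± 1329 in RS (n = 3; log2 -4.97, SE 0.52, adjusted p = 2.21e-08), and log2 -6.40 after GC correction to -4.07 with no filter over the alternatives. let-7b-5p (log2 -6.14, SE 0.50), let-7d-5p (-3.46, SE 0.48), let-7i-5p (-3.34, SE 0.49), let-7g-5p (-3.21, SE 0.44), let-7c-5p (-2.40, SE 0.40), let-7f-5p (-2.12, SE 0.48) and miR-98-5p (-1.71, SE 0.54) fell as well. The call of miR-98-5p was lost in 14 of the alternatives, 9 of them leaving out a library, with adjusted p from 2.70e-05 to 0.525 over all. That of let-7f-5p was lost without R1 replicate 1 (adjusted p = 0.178) or 2 (0.166) or with no filter (0.119), and that of let-7c-5p without R1 replicate 1 (0.0536). let-7e-5p stood at 0.19 (adjusted p = 0.758) and changed sign with total-count scaling (-0.47). The family sum was lower (log2 -3.22, SE 0.53, adjusted p = 1.49e-05, and log2 -4.71 after GC correction to -2.42 with no filter). The list held 8 decreases and 0 increases among 9, also when adjusted over the list alone (adjusted p = 6.71e-05, and adjusted p = 0.172 with an estimated correlation). Blood and endothelial markers took 0.0732% ± 0.00276 of counts in R1 (SD, n = 2) and 0.821% ± 0.668 in RS (n = 3), and mesenchymal markers 1.73% ± 0.124 and 4.81% ± 2.30.

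Of 806 miRNAs 427 changed, 271 higher and 156 lower in R1. With 0 counts in RS, miR-431-5p was at least 104-fold higher in R1, miR-291b-5p at least 85.4-fold, miR-302a-3p at least 75.6-fold, miR-376c-3p at least 69.4-fold and miR-363-5p at least 48.0-fold. With 0 counts in R1, miR-7210-5p was at least 34269-fold lower, miR-468-5p at least 20753-fold, miR-7214-5p at least 6791-fold, miR-7230-5p at least 2018-fold and novel_697 at least 988-fold.

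In the miR-290 cluster 17 of 18 members rose and 0 fell (adjusted p = 1.74e-08, and adjusted p = 0.172 with an estimated correlation), with miR-292a-5p at 8.70 (SE 1.33) and miR-293-5p at 8.64 (SE 1.12). miR-293-5p had 4, 220 and 7 counts in RS replicates 1, 2 and 3. Without RS replicate 2 the log2 differences of miR-292a-5p and miR-293-5p were 12.42 and 13.49, while the median difference of all miRNAs shifted by 0.77. In the miR-302 cluster 5 of 8 rose and 0 fell (adjusted p = 0.00862, and adjusted p = 0.248 with an estimated correlation), with miR-302a-5p at 7.81 (SE 0.69) and a ratio of 410 for miR-302b-3p (95% interval 113 to 3382). Their RS counts all lay in replicate 2, without which they were at least 253-fold and 183-fold higher in R1. In Dlk1-Dio3 80 of 92 rose and 0 fell (adjusted p = 2.19e-20, and adjusted p = 0.0738 with an estimated correlation), with miR-379-5p at 7.11 (SE 0.59) and miR-127-3p at 6.79 (SE 0.64), or 9.04 and 8.46 without RS replicate 2. All 6 members of the miR-183 cluster rose (adjusted p = 0.00862, and adjusted p = 0.172 with an estimated correlation), miR-183-5p by 4.40 (SE 0.53) and miR-182-5p by 4.38 (SE 0.54), or 5.27 and 5.37 without RS replicate 2. The list did not pass after thinning (adjusted p = 0.0574) or with only R1 and RS in the fit (0.0749). Of 23 miR-17/92 members 19 rose and 0 fell (adjusted p = 0.00284, and adjusted p = 0.373 with an estimated correlation), a call lost after GC correction (adjusted p = 0.168) and after thinning (0.0574). miR-93-5p was higher by 1.19 (SE 0.46, adjusted p = 0.0319), and stood at 2.35 without RS replicate 2. It was not called without RS replicate 1 (0.88, adjusted p = 0.0824), with upper-quartile (0.19, 0.760) or total-count scaling (0.37, 0.584), thinning (0.61, 0.221), only R1 and RS in the fit (0.78, 0.172) or the stricter filter (1.11, 0.0565), and changed sign after GC correction (-0.78). miR-25-3p stood at -0.43 (adjusted p = 0.402) and changed sign with the miR-290 cluster left out of the scaling (0.35). Adjusted over the list alone 6 miR-302, 83 Dlk1-Dio3 and 20 miR-17/92 members rose, and the other counts were the same.

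All 25 tested members of the X-linked cluster were lower in R1 than in RS (adjusted p = 8.77e-16, and adjusted p = 0.110 with an estimated correlation), miR-871-3p by log2 -7.16 (SE 0.74) and miR-881-3p by -6.57 (SE 0.82). In the miR-34 and miR-449 families 6 of 7 fell and 1 rose (adjusted p = 0.000174, and adjusted p = 0.110 with an estimated correlation), with miR-34b-3p at -10.95 (SE 0.66) and miR-34c-5p at -8.80 (SE 0.84). Of 3 miR-29 miRNAs 2 fell (adjusted p = 0.0218, and adjusted p = 0.172 with an estimated correlation), miR-29a-3p by 4.02 (SE 0.45) and miR-29b-3p by 4.98 (SE 0.95). That list did not pass after GC correction (adjusted p = 0.0594) or with antisense or identical features left out (0.0544). With GC correction its median went from -4.02 to -5.55 and all 3 members were lower, while the median of all miRNAs also shifted downward. Of 12 lineage markers 6 fell and 2 rose (adjusted p = 0.00862, and adjusted p = 0.110 with an estimated correlation), a call lost with only R1 and RS in the fit (0.0749), with miR-375-3p at -9.32 (SE 0.65), while miR-9-5p was not called (0.87, adjusted p = 0.0650) and changed sign with upper-quartile scaling (-0.12). Adjusted over the list alone 3 lineage markers rose and the other counts were the same.

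The lists that did not pass were miR-200 (3 of 7 rose, 0 fell, adjusted p = 0.229), miR-15/16 (2 of 7 rose, 3 fell, adjusted p = 0.187), the Sfmbt2 families (10 of 53 rose, 3 fell, adjusted p = 0.732, with a positive median and a test in the downward direction), other paternally expressed hosts (4 of 7 rose, 1 fell, adjusted p = 0.125), mesenchymal markers (1 of 11 rose, 3 fell, adjusted p = 0.187) and blood and endothelial markers (2 of 9 rose, 6 fell, adjusted p = 0.0617). Adjusted over the list alone 2 miR-200 members rose and 8 Sfmbt2 members rose and 2 fell, and the other counts were the same. Upper-quartile scaling shifted the median log2 difference by -0.99 and left 49.6% of called miRNAs higher, against 63.5% with TMM, and GC correction shifted it by -1.45 and left 38.2% higher. After GC correction 9 miR-17/92 members were higher and 3 lower, 0 Sfmbt2 members were higher and 16 lower, and 9 mesenchymal markers were lower, while with the miR-290 cluster left out of the scaling 22 Sfmbt2 members were higher and 1 lower. With the fit limited to R1 and RS 312 miRNAs passed.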

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

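The tests of explanations in this part were chosen after the results were seen.

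Among the 7 haploid libraries, 5 of 71 values checked had a library set apart from the rest by Dixon's criterion with a critical value of 0.568, and chance gives about 1 in 20. miR-335-5p was at 2.52 normalised CPM in A129-2 replicate 2, with 0.124 to 0.536 in the others. miR-19a-3p was at 4.02 in A129-17 replicate 1 (0 to 1.60 in the others), miR-93-5p at 4031 in A129-2 replicate 2 (2076 to 2869) and miR-106b-3p at 892 in A129-6 replicate 3 (1208 to 1432). The miR-15/16 family took 0.190% of counts in A129-2 replicate 1 and 0.0289% to 0.0879% in the others.

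Of 59 named miRNAs tested between the haploid lines 10 differed, of which the first 6 below had been named for their small p between lines, and of all 757 miRNAs 29 differed. Adjusted p was 0.0394 for miR-210-3p, miR-25-5p, miR-504-5p, miR-149-5p, miR-92a-2-5p, miR-3473b, miR-465c-5p and miR-871-3p, 0.0405 for miR-470-5p and 0.0406 for miR-465a-3p. The last 4 of these miRNAs belong to the X-linked cluster and were lowest in A129-2. miR-871-3p had 1867 ± 460.0 normalised CPM there, 8828 ± 5688 in A129-6 and 5972 ± 2550 in A129-17, and miR-470-5p had 1364 ± 303, 5497 ± 1967 and 3541 ± 2375 (SD, n = 2, 3 and 2).

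The X-linked cluster was higher in the haploid lines than in R1, and 16 of its 16 raised members still passed as higher after GC correction, which argues against GC-dependent recovery as the whole cause. Spermatids among the haploid cells would have to make up 6.85% of counts (median over 16 members, 0.499% to 75.9%), and the miR-34, miR-449 and miR-202 miRNAs stood at a median of 0.0101 of the level that such a share would bring, with miR-34c-5p at 142 CPM in the haploid lines, 256 in R1 and 199241 in RS. Of these 9 markers miR-34a-5p was the exception (ratio 61.2), being also expressed in R1, and a sort by DNA content would keep spermatids. The single X chromosome per autosome set of haploid cells would raise every member by about 1 above the autosomal median on the log2 scale. A first test did not decide this. The cluster median lay 1.15 above the autosomal median (95% bootstrap interval 0.155 to 3.25). That of 18 other X-linked loci lay 0.307 above it (interval -0.602 to 1.66, permutation p = 0.660). A second test, added after the first, found 15 of 22 members more than 2 standard errors from the expected value (9 above, 6 below). It cannot decide either. Log2 fold changes over 719 miRNAs had an SD of 2.73, against a median SE of 0.304 over the arms of 106 precursors. Most sets of miRNAs would therefore fail it, and X dosage remains open. Differences in origin or culture between the lines and R1 may also be behind the pattern and remain open and untested.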

How the results depend on the processing

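The alternatives that leave out the libraries with the lowest TMM factors, thin the ESC libraries, correct for GC, keep features with a GC estimate, or leave out antisense or identical features were chosen after seeing the data. Among the named miRNAs, calls kept direction and side of the threshold in 3067 combinations of result and alternative, lost the call in 90 and turned direction in 3, and for uncalled miRNAs 252 stayed, 59 passed and 61 turned direction. Calls of lists stayed in 674 combinations and were lost in 65, and uncalled lists stayed in 455, passed in 16 and turned in 22. The spermatid libraries held at most 243714 counts each, so low miRNAs were not detectable there at this depth. The causes of the changes given below were not tested, except that thinning leaves fewer counts and sums per line leave fewer samples.

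The 29 miRNAs that differed between lines became 0 with total counts, 82 with no filter, 4 with the stricter filter, 85 with DESeq2, 2 with all 12 libraries in the fit and 89 without the libraries with the lowest TMM factors. The 527 changed against RS became 336 with ESC libraries thinned. The let-7 sum against R1 was 0.94 with counts summed per line (adjusted p = 0.0605). With an estimated correlation 0, 0 and 0 lists passed, against 7 for haploid lines and R1, 11 for haploid lines and RS and 10 for R1 and RS. The stricter filter left 4 and 7 of the first 2 counts (in the second, 3 lists did not pass and miR-29 had too few members left to test), and GC correction left 4 of the first.

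Leaving out each library in turn gave 405 to 560 changed miRNAs for the haploid lines against R1, 329 to 489 for A129-2, 382 to 529 for A129-6 and 375 to 533 for A129-17, 465 to 534 for the haploid lines against RS and 389 to 461 for R1 against RS. Between lines the count ran from 0 to 80, 0 for A129-6 replicates 1 and 2, 6 and 9 for A129-2 replicates 2 and 1, 44 for A129-17 replicate 2 and 80 for A129-6 replicate 3. By pair it ran from 0 to 32 (A129-6 and A129-2), 0 to 70 (A129-17 and A129-2) and 0 to 40 (A129-17 and A129-6). The let-7 sums ran from 0.97 to 1.17, -1.68 to -1.31 and -3.45 to -2.51, and the lists from 7 to 8, 9 to 11 and 10 to 11. Where a group kept 1 library, that library was assumed to vary like the other groups.

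With the replicate block 534, 518 and 414 miRNAs changed (haploid lines against R1, haploid lines against RS, R1 against RS) and 72 differed between lines. Libraries of the same number in different ESC groups correlated from -0.177 to 0.139 (mean -0.0417, other pairs 0.0278). These are correlations of deviations from group means, which mirror each other in a group of 2 libraries. The mean of the other pairs is therefore tied to that of the same-number pairs and is no separate reference. The same-number pairs showed no shared positive correlation, and the numbers are not treated as pairs.

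The set test of some uncalled lists turned direction, with these median log2 differences. Against R1 these were the miR-290 cluster with the higher arm only (-0.22) or GC correction (-0.20), the miR-34 and miR-449 families with total counts (-0.079) or GC correction (0.57) and from -0.93 to 0.26 with a library left out (0.26 without R1 replicate 1), other paternally expressed hosts with the stricter filter (-0.20), and, with GC correction, miR-302 (-0.29), mesenchymal (-0.16) and lineage markers (-0.44). With GC correction they were also miR-183 in the haploid lines against RS (0.79) and miR-200 in R1 against RS (-0.69). For Sfmbt2 in R1 against RS it turned with miR-290 out of the scaling (1.43), no filter (1.70), the lowest TMM factors out (1.15) and antisense out (1.40), and the median ran from 0.54 to 1.63 with a library left out.

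Log2 differences of haploid lines against R1 turned sign for let-7f-5p with RLE and DESeq2 (both -0.030), let-7g-5p with all 12 libraries (0.35) and GC correction (0.035), and miR-98-5p with upper quartile (0.29), stricter filter (0.35), all 12 libraries (0.82), GC correction (0.71) and features with a GC estimate (0.0073), and miR-98-5p ran from -0.11 to 0.023 with a library left out. miR-106b-3p turned with RLE and DESeq2 (both -0.058) and GC correction (-0.74). Upper quartile, stricter filter, all 12 libraries and GC correction gave 0.10, 0.16, 0.64 and 0.32 for miR-183-3p and 0.024, 0.067, 0.57 and 0.23 for miR-541-5p, and all 12 libraries gave 0.42 for miR-467a-5p and miR-467b-5p.

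Against RS, let-7c-5p in the haploid lines turned with RLE (-0.089), DESeq2 (-0.089), upper quartile (-1.24), total count (-1.39), stricter filter (-0.15), GC correction (-1.02), thinning (-0.71) and sums per line (-0.45). miR-467a-5p and miR-467b-5p turned with upper quartile (-1.11), total count (-1.21), stricter filter (-0.021), GC correction (-1.91), thinning (-0.50 and -0.47) and sums per line (-0.37), and miR-98-5p ran from -1.10 to 0.039 with a library left out. In R1 against RS let-7e-5p turned with upper quartile (-0.81), total count (-0.47), GC correction (-1.18), thinning (-0.42) and the fit limited to both groups (-0.22). miR-25-3p turned with miR-290 out of the scaling (0.35), no filter (0.33), the lowest TMM factors out (0.067) and antisense out (0.24), and ran from -0.49 to 0.69 with a library left out. miR-93-5p turned with GC correction (-0.78), and miR-9-5p with upper quartile (-0.12) and GC correction (-0.55).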

Other observations

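All tests of explanations in this part were chosen after the results were seen, except the count over splits of the libraries. The miRNAs of the next paragraph were likewise chosen after their values were seen.

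Abundant miRNAs outside the lists also differed between haploid lines and R1. miR-7a-5p fell from 49880 ± 9204 normalised CPM in R1 (SD, n = 2) to 2196 ± 406 in the haploid lines (SD of 3 lines; log2 -4.52, SE 0.37). miR-148a-3p fell from 29959 ± 502 to 1593 ± 483 (log2 -4.27, SE 0.19) and miR-21a-5p from 50224 ± 2521 to 5187 ± 398 (log2 -3.28, SE 0.19), while miR-151-3p rose from 1162 ± 90.1 to 10585 ± 3407 (log2 3.14, SE 0.33). The log2 fold changes of the 5p and 3p arms of a precursor went together in part (Pearson's r 0.597 over 106 precursors), but some arms went apart. Among 69 precursors with both arms past the threshold, 15 had arms that changed in opposite directions. After GC correction 10 of 65 did, 7 of them among the 15. In 3 of these 7, miR-291a-5p rose (log2 1.57, SE 0.28) and miR-291a-3p fell (-1.99, SE 0.19), miR-433-3p rose (2.35, SE 0.26) and miR-433-5p fell (-2.75, SE 0.29), and miR-455-3p rose (3.91, SE 0.50) and miR-455-5p fell (-1.36, SE 0.34). The decrease of miR-455-5p was not called with all 12 libraries in the fit (-0.51, adjusted p = 0.273) or without R1 replicate 1 (0.0614), with adjusted p from 3.39e-05 to 0.273 over the alternatives.

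The fold changes between haploid lines and R1 went with the estimated GC content of the arm (Spearman's rho 0.290 across miRNAs). After a correction for GC in each library 68.7% of the miRNAs with an estimate still passed, which argues against GC-dependent recovery as the whole cause. Transcription of the precursors as the whole cause is also argued against. Of precursors with both arms past the threshold 21.7% had arms going in opposite directions (15.4% after GC correction). The difference between arms went with their difference in GC over 106 precursors (rho 0.493, permutation p = 1e-05, the smallest the permutations can give). After GC correction this rho was 0.240. The correction, based on estimated arm GC, was thus incomplete, and GC-dependent recovery may still be part of the corrected values. A batch of library or RNA preparation that coincides with the groups cannot be told apart from them, because the labels name no batch. A difference in arm selection between the lines may be a further source and was not tested.

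RS replicate 2 held 1052 counts of the miR-290 cluster, against 24 and 72 in the other spermatid libraries. The shares of its members within the cluster lay close to those of R1 (median log2 distance 0.126) and farther from A129-2, A129-6 and A129-17 (1.03, 1.13 and 1.30), for A129-2 a difference short of the 1 on the log2 scale that was set to decide against the haploid lines. A test added afterwards found a ratio of miR-293-5p to miR-292a-5p of 0.733 (95% interval 0.613 to 0.876), against 0.652 and 0.668 in R1 and at most 0.00922 in a haploid library, which argues against reads or cells of the haploid lines. On few counts, the ratio was also high in RS replicate 1 (1.33, from 4 and 3 counts) and replicate 3 (0.241, from 7 and 29 counts). A high ratio was therefore not particular to replicate 2. A candidate explanation is carry-over of R1 reads or cells at 1.36% of the library. That share would bring 6.39 counts of the miR-302 cluster, and 8 were found (0 in the other spermatid libraries). It would also bring 185 counts of Dlk1-Dio3, where 711 were found against 455 in RS replicate 1 and 429 in replicate 3. These libraries differ in depth. As a share of counts Dlk1-Dio3 took 0.458% in RS replicate 2, 0.187% in replicate 1 and 0.257% in replicate 3. This excess was larger than that carry-over would bring. No biological explanation was tested. The sort by Hoechst fluorescence was meant to collect haploid cells, but its purity was not tested. Mesenchymal markers took 7.31%, 2.77% and 4.36% of counts in RS replicates 1, 2 and 3, so diploid testis cells were not excluded.

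In the comparison of haploid lines with RS, 100 of the 120 splits of the 10 libraries into 7 and 3 were drawn. In a fit of those libraries the real split gave 496 changed miRNAs and the highest of the others 1, so 1 of the 100 splits gave as many. Every other split put spermatids and haploid ESC together in at least 1 group, which widens the spread within groups and leaves few calls. The 7 haploid libraries also come from 3 lines and cannot be exchanged freely. The count over splits therefore cannot exclude chance assignment of the libraries.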
